A study of Homo sapiens with 4 samples.

How the data were processed

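The series profiled Shep2 cells, a substrate-adherent human neuroblastoma line, by RNA sequencing. Per the labels, the cells carried either a control short hairpin (shControl) or hairpin number 4 against GDE2 (shGDE2), the phosphodiesterase encoded by GDPD5, as stable knockdown lines. Cells were grown for 2 days in 10-cm dishes in DMEM with 10% serum at 37°C and 5% CO2, RNA was extracted with Trizol, and libraries were made with Kapa reagents, per the labels' protocols. Each group had 2 libraries. The labels give no separate culture, day or clone for any library, so the p-values measure only the spread between these libraries, which may be technical, and only 1 hairpin and 1 control line were compared.

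The deposited table gave 1 whole-number read count per Ensembl gene and library. TopHat2 2.0.12, Bowtie, HTSeq and the genome build hg38 are named, with no role or settings, per the submitters' processing notes. The annotation release, the strand setting of the counting and any read filter are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense or overlapping neighbour cannot be told apart where they overlap. Reads shared between near-identical genes (histones, ribosomal proteins and their pseudogenes, mitochondrial genes and their nuclear copies) make those counts uncertain. The table held 25110 genes, each with a count in at least 1 library, and 24480 of the identifiers were found in the gene name table used here. All columns of per-library values were used.

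Library totals were 10586607 and 10719088 counts in shControl and 12317011 and 13161203 in shGDE2. Genes were kept with edgeR's filterByExpr at its minimum count of 10, which left 13583. Libraries were scaled by edgeR's TMM method, with factors from 0.994 to 1.01. Differences were tested with edgeR 4.0.16 (R 4.3.3), by the robust quasi-likelihood F test with group as the only term and 2 residual degrees of freedom, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change is shGDE2 over shControl. Its standard error is the absolute log2 fold change divided by the square root of F. Values per group are TMM-scaled counts per 1e6 counts (CPM), as mean ± SD over 2 libraries. The biological coefficient of variation was 0.0262, and 91.8% of the genes took an infinite prior, so their spread was set by the trend across genes. The smallest adjusted p-values, such as those of FN1 and MID1, fell below the smallest number the software holds and are not printed.

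Before the data were examined, 38 gene lists, the tests, the alternatives and the rule for naming genes were written down. The rule takes GDPD5, the other members of its family and the glypicans, then the 12 largest increases and 12 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, and then up to 4 members per list with the smallest adjusted p, or up to 2 by level where none passed. Genes known only by a clone name or without a description, and pseudogenes of mitochondrial or ribosomal protein genes, were not eligible. List members were tested together with edgeR's camera at a preset correlation between genes of 0.01, for lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the 37 such lists. Camera with an estimated correlation and fry were run beside it.

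Further steps were chosen after the fold changes had been seen. Neighbouring genes with a mean of at least 5 CPM, 10827 in all, were searched by recursive segmentation for runs of at least 20 genes whose log2 fold changes, limited to between -1 and 1, were shifted together, with 999 permutations of the gene order at a threshold of 0.001 and a median at least 0.15 away from that of all genes. The GC content and length of transcripts came from GENCODE 29 on GRCh38. The 3′ UTRs of 10152 genes (at least 5 CPM and 50 bases) were searched for each of the 16384 words of 7 bases. The log2 fold change, limited to between -1 and 1, was regressed on the presence of each word. UTR length, UTR and transcript GC content and expression level were covariates, and 1000 permutations of the residuals gave the range of the largest absolute z. Intervals of medians are 95% bootstrap intervals from 1000 draws over genes. Genes are not independent replicates, so such intervals describe these libraries.

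The count test was tested on simulated data with the real means, library sizes and dispersion trend over 13583 genes, of which 200 were changed in this comparison. The edgeR test recovered 52% of the genes changed 1.25-fold, 80% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, and 5.33% of its calls were false. DESeq2 1.42.0 recovered 28%, 62%, 82% and 92%, with 0.752% false calls. Camera with the preset correlation called 4 of 4 planted lists and 0 of 36 others, and with an estimated correlation it called 0 of 4 planted lists. Each list held 20 genes, and in the planted lists only some of them were raised, 1.25-fold or 1.5-fold. Lists with larger shifts were not planted, so whether an estimated correlation would miss those was not tested. The simulated genes were drawn independently, so this simulation cannot show how often the preset falsely calls lists of correlated genes. In the real data the estimated correlation was 0.85 for the mitochondrially encoded mRNAs and 0.50 for the ribosomal proteins. It was also above the preset for the glypicans (0.33), the extracellular matrix (0.28) and the TGF-beta and BMP list (0.21). For other called lists it lay below the preset, as for the integrins (-0.0033) and p53 targets (-0.030). The segmentation, run on 10827 genes in shuffled order, found 8 of 10 planted runs of 60 genes raised by 0.3 and 0 runs where none was planted. In the word search a word planted with a decrease of 0.1 took rank 1 of 16384. Alternatives were other scalings (DESeq2's size factors, total counts only), other tests (DESeq2, limma-voom 3.58.1), other filters and thresholds, a test against a fold of 1.2, the replicate number as a block and each library left out in turn. Alternatives added later are named as such. Not every gene looked at after the values were seen is reported.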

Results

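Gene expression was measured by RNA sequencing in Shep2 neuroblastoma cells with stable knockdown of GDE2 and in control cells. GDE2, encoded by GDPD5, is a multipass membrane phosphodiesterase that cleaves glycosylphosphatidylinositol (GPI) anchors and is known for promoting neuronal differentiation. The comparison asks which transcripts differ when this enzyme is depleted. Each group held 2 libraries, with 10586607 and 10719088 counts in shControl and 12317011 and 13161203 in shGDE2. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.71 between the shControl libraries and 2.00 between the shGDE2 libraries. Libraries of different groups gave 20.6 to 22.3.

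The targeted transcript was lower in both knockdown libraries. GDPD5 (ENSG00000158555, chromosome 11, 75434640 to 75525903 on hg38) had 251 and 315 counts in shControl and 159 and 184 in shGDE2. Its level was 26.7 ± 4.1 CPM in shControl and 13.4 ± 0.66 CPM in shGDE2 (SD, n = 2), a log2 fold change of -0.99 ± 0.10 (SE, edgeR adjusted p = 4.73e-20). Within the same enzyme family, GDE1 rose by a log2 fold change of 0.20 ± 0.05 (adjusted p = 0.000464), a call that DESeq2 did not make (adjusted p = 0.0721) and that was also lost against a fold of 1.2. GDPD1 (0.31 ± 0.30, adjusted p = 0.436) and GDPD3 (-0.02 ± 0.40, adjusted p = 0.981) were not past the threshold. GDPD2 had 0 to 3 counts per library and was not tested.

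Glypicans are GPI-anchored heparan sulfate proteoglycans and include known substrates of this enzyme family. All 3 glypicans with enough counts rose. GPC1 went from 718 ± 27 to 1012 ± 9.6 CPM (log2 fold change 0.50 ± 0.03, adjusted p = 7.97e-47), GPC6 from 42.3 ± 0.0073 to 58.8 ± 2.2 CPM (0.48 ± 0.07, adjusted p = 1.93e-11) and GPC4 from 14.8 ± 0.23 to 22.9 ± 0.43 CPM (0.63 ± 0.11, adjusted p = 3.03e-08). As a list the glypicans ranked above other genes (camera adjusted p = 0.00201), with an adjusted p = 0.364 with an estimated correlation. Of the other GPI-anchored proteins 12 of 28 tested members were lower, 4 were higher and 12 were not past the threshold, with a median log2 fold change of -0.10. NT5E (CD73, the ectonucleotidase that makes adenosine) fell from 648 ± 5.5 to 341 ± 11 CPM, SEMA7A by 1.33 and RGMB by 0.99 on the log2 scale, whereas GFRA1, the GDNF co-receptor, rose from 21.6 ± 3.9 to 75.1 ± 2.2 CPM. The list ranked low (camera adjusted p = 0.00162), with an adjusted p = 0.285 with an estimated correlation.

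**Figure D1:**
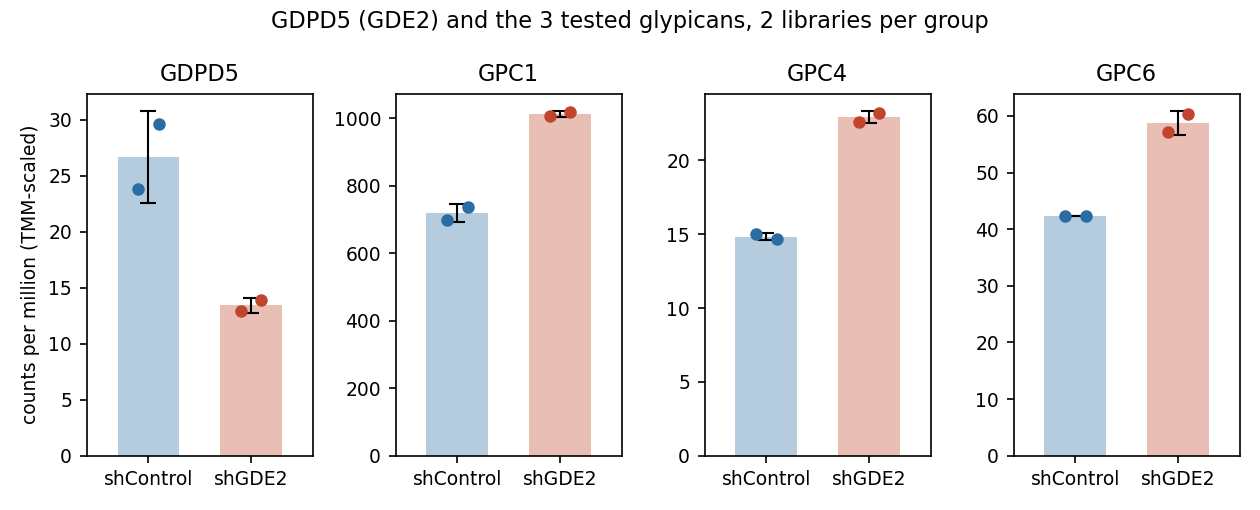
TMM-scaled CPM of GDPD5, GPC1, GPC4 and GPC6 in shControl and shGDE2 cells. Bars are means, lines are 1 SD and points are the 2 libraries of each group. GDPD5 falls from 26.7 to 13.4 CPM and the 3 glypicans rise.

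Across the transcriptome 5122 of 13583 tested genes (37.7%) passed the threshold, 2559 higher and 2563 lower in shGDE2. Most changes were small: 270 genes were at least 2-fold higher and 286 at least 2-fold lower, and 42 and 55 changed at least 4-fold. The groups did not overlap for 65.9% of the tested genes, where chance gives 33.3% for 2 against 2. The count depended on the test: DESeq2 called 2491 genes (1170 higher, 1321 lower), and testing against a fold of 1.2 left 1569 (726 higher, 843 lower).

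Among genes with a mean of at least 5 CPM, the largest increases included secreted and surface proteins. COLEC12, a scavenger receptor of the collectin family (chromosome 18, 319361 to 500722), rose 9.83-fold, from 4.39 ± 0.84 to 43.2 ± 2.0 CPM. MMP3 (stromelysin-1) rose 5.56-fold, SLITRK5, a neuronal transmembrane protein, 5.43-fold, and ALDH1A1, an enzyme that makes retinoic acid, from 26.5 ± 2.1 to 103 ± 0.83 CPM. MID1, a microtubule-associated ubiquitin ligase, rose from 105 ± 3.8 to 402 ± 6.0 CPM. The other 7 were PPP2R2C, C9orf84, the adherens junction protein PLEKHA7, the kinesin KIF26B, complement C3, the actin-binding protein SYNPO2 and the peptidase DPP4, with log2 fold changes from 1.90 to 2.17.

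At the same minimum level, the largest decrease was that of GRPR, the gastrin-releasing peptide receptor, which fell from 21.9 ± 0.076 to 1.56 ± 0.14 CPM (log2 fold change -3.80 ± 0.18). PTPRC, which encodes the leukocyte phosphatase CD45, fell from 25.1 ± 0.76 to 2.30 ± 0.37 CPM. NTM, a GPI-anchored adhesion molecule of neurons, fell by 3.03 on the log2 scale, and the synaptic protein ELFN1 from 63.6 ± 3.3 to 8.92 ± 1.1 CPM. HHIP, the hedgehog-binding antagonist of that pathway, fell from 157 ± 1.3 to 23.2 ± 3.6 CPM. Genes of cell-matrix contact were ITGA11, LAMA4 and COL13A1, with log2 fold changes of -2.80, -2.80 and -2.65. The remaining genes were the imprinted noncoding RNA H19, the endothelial receptor TIE1, GGT5 and the calcium channel CACNA1C. The largest adjusted p of these 24 genes was 9.03e-17 (edgeR). HHIP overlaps in part the antisense gene HHIP-AS1, a gene picked after its values were seen, which also fell (log2 fold change -2.32). Reads from the stretch they share cannot be told apart. Below 5 CPM larger folds occurred, as for the homeobox gene MEOX2, also picked after its values were seen, with 17 and 21 counts in shControl and 0 in both shGDE2 libraries.

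**Figure D2:**
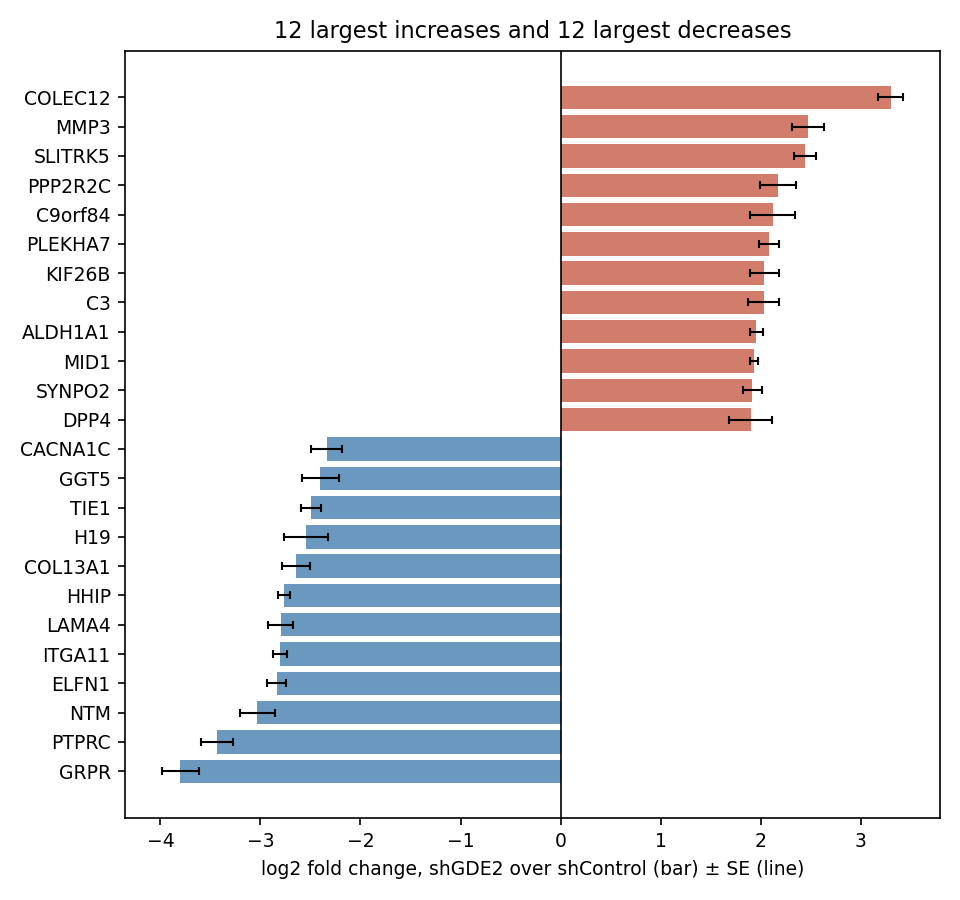
Log2 fold changes of the 12 largest increases and 12 largest decreases in shGDE2 over shControl among genes with a mean of at least 5 CPM. Bars are fitted values and lines are 1 SE; they run from -3.80 for GRPR to 3.30 for COLEC12.

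Extracellular matrix genes fell more often than they rose. Of 38 tested, 21 were lower, 12 higher and 5 not past the threshold, and the list ranked low (camera adjusted p = 8.34e-16), with an adjusted p = 0.333 with an estimated correlation. Fibronectin (FN1), among the most abundant transcripts of these cells, fell from 7533 ± 177 to 2085 ± 24 CPM, COL6A3 from 456 ± 14 to 99.4 ± 2.4, FBN1 (fibrillin-1) from 757 ± 9.3 to 322 ± 1.4 and THBS1 (thrombospondin-1) from 4313 ± 151 to 2131 ± 22 CPM. Integrins, the receptors for such ligands, were lower in 9 of 15 cases and higher in 3 (camera adjusted p = 5.14e-06, adjusted p = 0.285 with an estimated correlation). ITGA11, ITGA10 and ITGA6 fell by 2.80, 2.28 and 0.67 on the log2 scale, and ITGAV rose by 0.66. Matrix proteases and their inhibitors went both ways, with 6 of 24 higher, MMP3 among them, and 8 lower, such as ADAM12 (-1.08) and MMP2 (-0.44), and were called by fry (adjusted p = 0.0374) but not by camera (adjusted p = 0.345).

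Genes of mesenchymal neuroblastoma identity, the state that Shep2 cells are known for, were lower in 17 of 31 cases and higher in 3 (camera adjusted p = 2.48e-10), with an adjusted p = 0.285 with an estimated correlation. VIM (vimentin) fell from 5538 ± 214 to 3265 ± 110 CPM, CDH11 (cadherin-11) from 52.9 ± 3.3 to 11.1 ± 0.12 CPM, and the transcription factor gene CREB3L2 by 0.69 on the log2 scale. The adrenergic identity list did not stand apart (3 of 9 higher, 2 lower, camera adjusted p = 0.977), with MYCN higher by a log2 fold change of 0.60 ± 0.10 and TBX2 lower by 1.16 on the log2 scale. Neuronal differentiation markers were lower in 6 of 14 cases and higher in 1 (called by fry, adjusted p = 0.0111, but not by camera, adjusted p = 0.372; with DESeq2 2 lower and 0 higher), and the neuronal enolase ENO2 fell from 21.4 ± 1.0 to 12.6 ± 1.6 CPM. Neural crest and stemness genes (4 of 13 higher, 2 lower, adjusted p = 0.700) and glial markers (0 of 3 past the threshold, adjusted p = 0.977) were called by neither test.

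Markers of other cell types moved with these groups. Epithelial markers were higher in 5 of 8 cases and lower in 0 (camera adjusted p = 1.84e-08, adjusted p = 0.285 with an estimated correlation), and keratins KRT18 and KRT8 went from 165 ± 0.87 to 450 ± 3.8 and from 73.5 ± 2.8 to 134 ± 2.9 CPM. Endothelial markers were lower in 3 of 5 cases (camera adjusted p = 2.80e-06, adjusted p = 0.285 with an estimated correlation): TIE1 fell from 48.9 ± 0.15 to 8.68 ± 0.53 CPM, the VEGF receptor gene FLT1 from 98.1 ± 6.6 to 49.9 ± 1.1, and PECAM1 fell as well. The call of PECAM1 was lost without shControl replicate 2 (adjusted p = 0.0548). Of the haematopoietic list only PTPRC and CSF1R had enough counts. Both were lower, but CSF1R (2.41 ± 0.59 and 1.11 ± 0.50 CPM) lost its call with DESeq2 and without either shControl replicate 2 or shGDE2 replicate 2 (adjusted p = 0.169, 0.193 and 0.221).

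Signalling genes fell in 3 further lists. Immediate-early genes and feedback regulators of growth factor signalling were lower in 14 of 26 cases and higher in 1 (camera adjusted p = 2.80e-06, adjusted p = 0.285 with an estimated correlation), with KLF6 at -0.75, JUN at -0.69, IER2 at -0.70 and the ERK pathway inhibitor SPRY4 at -0.85 on the log2 scale. Wnt targets and regulators were lower in 7 of 13 cases and higher in 2 (camera adjusted p = 0.000287, adjusted p = 0.285 with an estimated correlation). The ligand genes WNT5A and WNT5B fell by 0.72 and 1.03, DKK3, an abundant secreted protein of the Dickkopf family, fell from 655 ± 24 to 330 ± 2.6 CPM, and the Wnt inhibitor gene DKK1 rose by a log2 fold change of 0.32, a call lost against a fold of 1.2. With DESeq2 4 Wnt members were lower and 1 higher. The TGF-beta and BMP list was lower in 9 of 24 cases and higher in 4 (camera adjusted p = 2.87e-05, adjusted p = 0.434 with an estimated correlation). Its most changed members were secreted: the activin antagonist FST fell from 203 ± 2.8 to 55.2 ± 0.30 CPM, the activin subunit INHBA from 163 ± 1.3 to 46.9 ± 1.0 and the BMP antagonist GREM1 from 46.2 ± 3.4 to 17.4 ± 1.7, while TGFBI rose by 0.44 on the log2 scale.

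In the opposite direction, NF-kB targets and inflammatory cytokines were higher in 15 of 21 cases and lower in 2 (camera adjusted p = 6.12e-06, adjusted p = 0.285 with an estimated correlation). TNFAIP2 rose from 14.3 ± 0.36 to 35.4 ± 2.6 CPM, NFKB2 from 91.2 ± 1.7 to 140 ± 0.98 and BIRC3, an inhibitor of apoptosis, from 22.1 ± 1.5 to 44.2 ± 1.8, and the adhesion molecule VCAM1 fell by 0.48 on the log2 scale. Retinoic acid response genes were higher in 5 of 9 cases and lower in 0 (camera adjusted p = 1.20e-05, adjusted p = 0.292 with an estimated correlation). Besides ALDH1A1, the retinoid-binding CRABP2 rose by 1.02 and CYP26B1, which degrades retinoic acid, by 0.61. The p53 targets were higher in 10 of 23 cases and lower in 1 (camera adjusted p = 0.00309, adjusted p = 0.290 with an estimated correlation). GDF15 rose from 69.3 ± 5.8 to 131 ± 3.0 CPM, and SESN1 and BTG2 rose by 0.59 and 0.65 on the log2 scale.

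Transcripts that often track RNA composition were also higher. Of the mitochondrially encoded mRNAs 12 of 13 were higher and 0 lower, with a median log2 fold change of 0.43 (camera adjusted p = 1.38e-10, adjusted p = 0.434 with an estimated correlation), and MT-CO3 went from 2093 ± 29 to 3051 ± 5.0 CPM. Mitochondrial genes took 2.90% and 2.61% of the shControl counts and 3.63% and 3.39% of the shGDE2 counts. Ribosomal protein genes were higher in 54 of 77 cases and lower in 0, by a median of 0.12 (camera adjusted p = 1.68e-05, adjusted p = 0.740 with an estimated correlation), and in 31 with DESeq2. Replication-dependent histones were higher in 6 of 11 cases and lower in 0 (camera adjusted p = 0.0418, adjusted p = 0.434 with an estimated correlation), a call lost without shControl replicate 2 and without shGDE2 replicate 1. HIST1H1C rose by 0.66 on the log2 scale. Noncoding RNAs without a usual poly(A) tail had 0 of 4 members past the threshold (adjusted p = 0.965), with MALAT1 at 1594 ± 282 and 1395 ± 271 CPM.

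**Figure D3:**
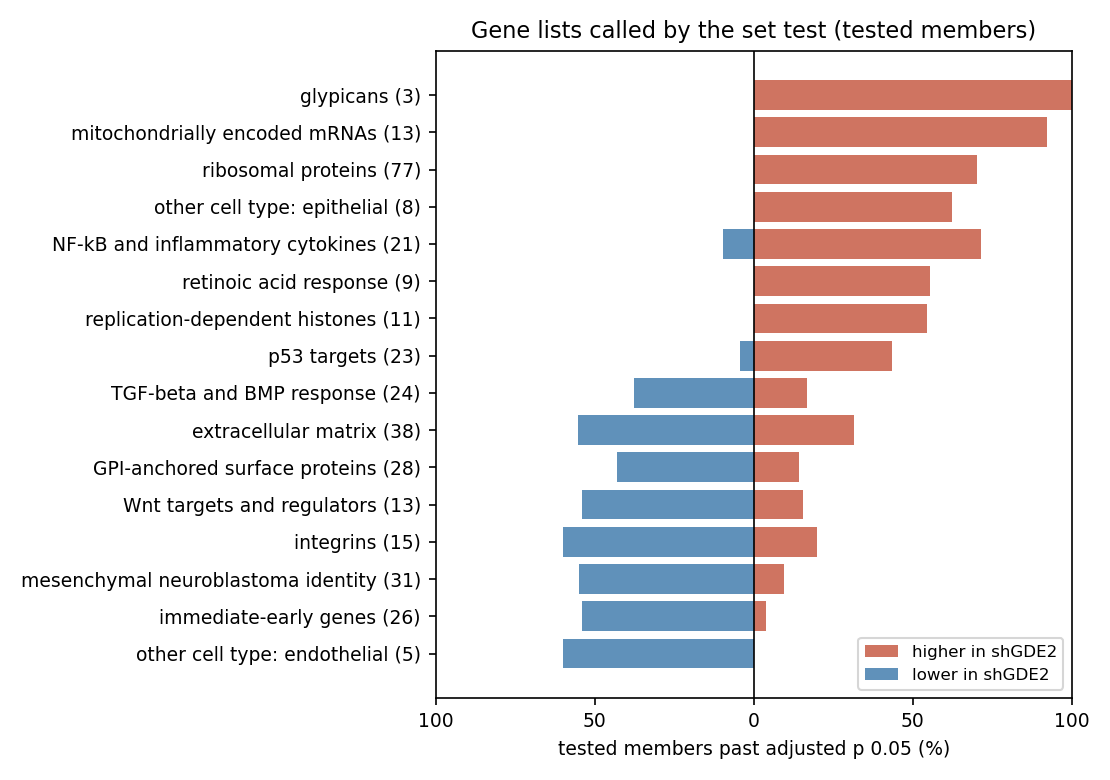
Share of the tested members of each list called by camera that were higher (right) or lower (left) in shGDE2, in percent, with the number tested in brackets. Of the 16 lists, 8 rank high and 8 rank low.

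The other 14 tested lists were not called by camera, with adjusted p-values of 0.0935 and above. Cell cycle genes were split, with 7 of 34 G1/S genes higher and 7 lower, RRM1 at -0.44 among them, and 2 of 35 G2/M genes higher and 8 lower, such as ANLN (-0.35). Axon guidance genes moved both ways (10 of 37 higher, 11 lower), with SEMA5A and UNC5C up by 1.70 and 1.68 and EPHB2 and NRP1 down by 1.04 and 0.61 on the log2 scale. Neurotrophin and GDNF signalling had 4 of 9 members higher and 2 lower, the Notch pathway 2 of 12 and 6, with JAG1 at -0.53, and YAP/TAZ targets 11 of 21 and 6, with TGFB2 at 1.18 and AXL at -0.61. Actomyosin genes were higher in 12 of 22 cases and lower in 5, interferon-stimulated genes in 3 of 33 and 9, stress response genes in 7 of 23 and 5, heat shock proteins in 4 of 13 and 4, and lipid synthesis genes in 4 of 29 and 6. Glycerophospholipid metabolism had 8 of 27 members higher and 6 lower, among them the lysophospholipase D gene ENPP2 (6.37 ± 0.64 and 1.61 ± 0.031 CPM). Hypoxia and glycolysis genes (8 of 23 higher, 7 lower), whose median changed sign with total-count scaling, and small RNA machinery (3 of 13 higher, 4 lower) complete the set. DESeq2 called fewer members in most of these lists: 0 heat shock proteins were higher and 4 lower, 2 hypoxia and glycolysis genes higher and 6 lower, 1 interferon-stimulated gene higher and 2 lower, and 0 G2/M genes higher and 2 lower. It called 3 G1/S genes higher and 4 lower, 3 lipid synthesis genes higher and 2 lower, and 1 small RNA machinery gene in each direction. The median, mean and test differed in sign for the GDPD family, glycerophospholipid metabolism, axon guidance, G1/S, matrix proteases and the noncoding RNAs. Adjusted over the list alone, the counts rose to 58 ribosomal proteins and 8 histones higher and 13 GPI-anchored proteins lower, and moved by at most 2 genes per direction in any other list.

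Fold changes were also arranged along the chromosomes. In a search made after the fold changes had been seen, 7 runs of neighbouring genes were shifted together. The longest, on chromosome 1 from 150293720 to 248919946 (hg38), held 453 genes with a median log2 fold change of 0.22 (95% interval 0.19 to 0.24), and 83.4% of them had a fold change above 1. Runs on chromosome 7 (1688119 to 45768985, 154 genes, median -0.21), chromosome 12 (120686869 to 123272334, 30 genes, median -0.44) and chromosome 19 (9810267 to 13763296, 73 genes, median -0.37) were low. Those on chromosome 8 (70573442 to 80874781, 20 genes, median 0.25), chromosome 16 (87383995 to 89557768, 20 genes, median 0.30) and chromosome 22 (43166622 to 50801309, 46 genes, median 0.23) were high. Every one of the 30 genes on chromosome 12 had a fold change below 1. The ends of the runs were chosen from these same fold changes, so the medians, intervals and shares are in part set by that choice. Medians of 40 neighbouring genes ranged from -0.37 to 0.35, against -0.19 to 0.19 in 200 shuffles of the gene order. The runs held 994 of the tested genes and 597 of the 5122 changed ones. Of the genes named above, KIF26B, PTPRC, ELFN1, CRABP2, BTG2, IER2, ANLN, INHBA, MEOX2 and TGFB2 lie inside them.

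**Figure D4:**
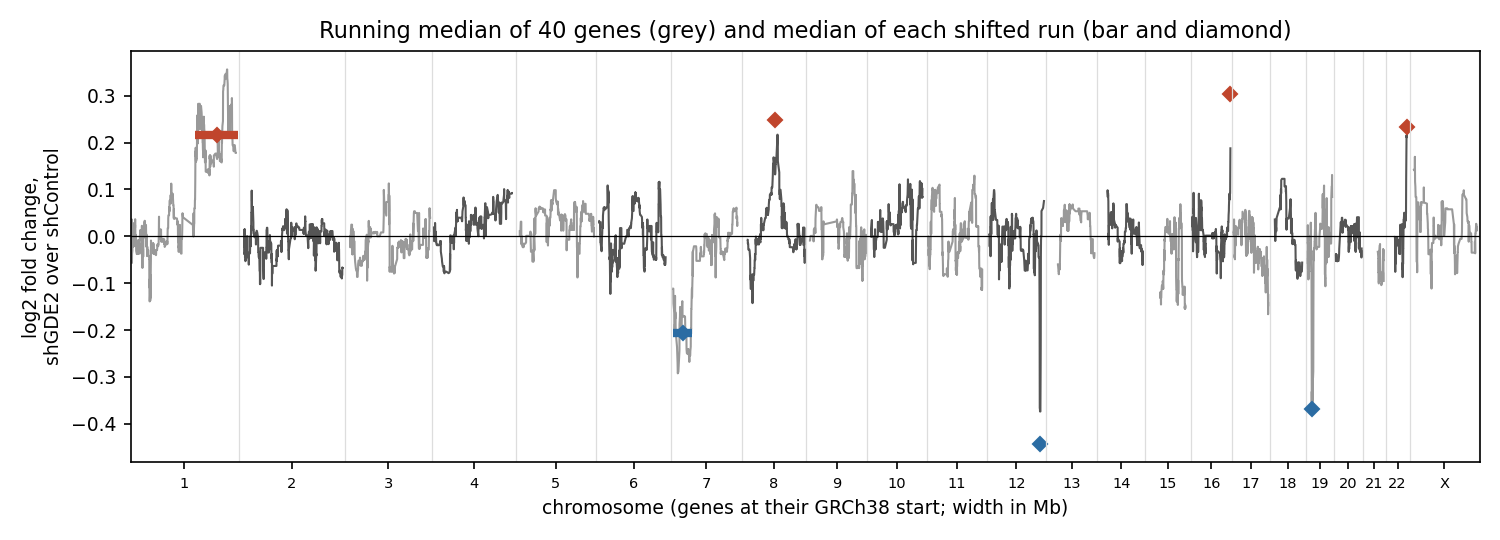
Running median over 40 neighbouring genes of the log2 fold change in shGDE2 over shControl along the chromosomes (grey lines), with the median of each of the 7 shifted runs as a coloured bar and diamond. The runs lie between -0.44 on chromosome 12 and 0.30 on chromosome 16.

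The fold change also varied with short words in the 3′ UTR. Of all 16384 words of 7 bases, ATGACAC and TGACACA went with the lowest fold changes (z = -9.23 and -8.37), and the largest absolute z in 1000 permutations was 5.89. The 2 words overlap in 6 bases and together make ATGACACA. The 261 genes with ATGACACA in the 3′ UTR had a median log2 fold change of -0.15 (95% interval -0.18 to -0.10), and 45.2% of them were lower. The median was -0.05 for 456 genes with ATGACAC alone and -0.04 for 717 genes with TGACACA alone, of which 30.9% and 28.3% were lower. It was 0.00030 for 1136 genes with TGACAC only and 0.01 for 7582 genes with no such word, of which 19.4% were lower. The words were picked from the fold changes of these same genes, so the medians, intervals and shares are in part set by that choice. The coding sequence of GDPD5 holds ATGACACA in its last exon (exon 17 of transcript GDPD5-201, chromosome 11, 75435591 to 75435598 on GRCh38, minus strand), within CAGACAACAGTTATGACACATATG. Its 3′ UTR holds TGACACA (75435472 to 75435478). Genes named above with the long word in the 3′ UTR are ITGA11, CREB3L2 and ADAM12, which fell, and SYNPO2 and SEMA5A, which rose. Those with a word of 7 bases are SLITRK5, GPC1, GPC6, NT5E, MYCN, NRP1, TGFB2, GREM1 and THBS1.

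**Figure D5:**
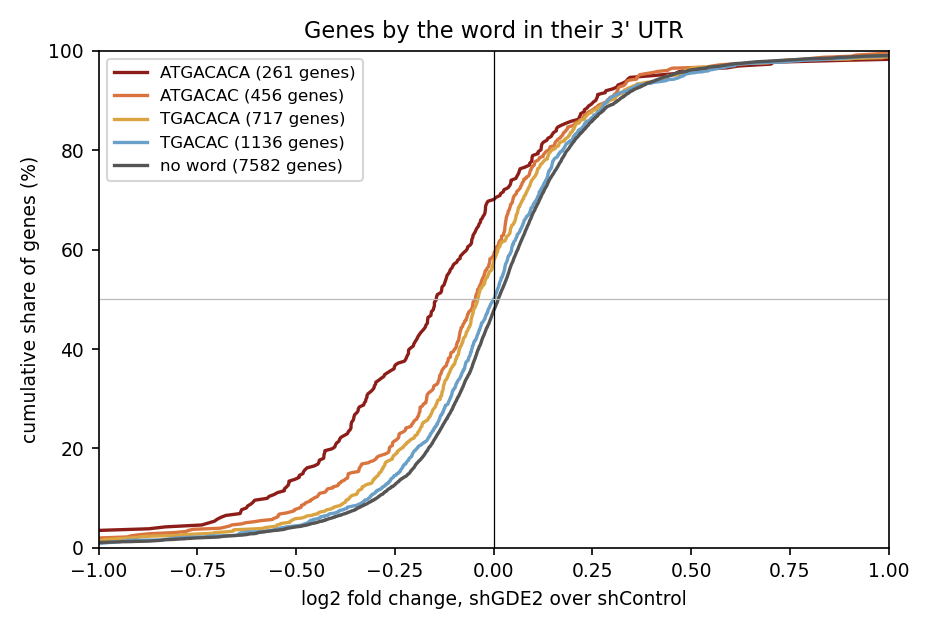
Cumulative share of genes (percent) against the log2 fold change in shGDE2 over shControl, for genes grouped by the longest of the listed words in their 3′ UTR. The curve of the 261 genes with ATGACACA lies furthest left, with a median of -0.15 against 0.01 for the 7582 genes with no such word.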

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

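The DESeq2 alternative with a local dispersion trend and the fits without genes of the shifted runs or with a word in the 3′ UTR were chosen after seeing the data. The count of 5122 changed genes stayed within 1.5 times under other scalings, limma-voom, other filters and an adjusted p under 0.01 (3885 to 5153), and lay between 3879 and 4100 with 1 library left out, where the lone library of a group is assumed to vary like the other group. It fell to 2491 (1170 higher, 1321 lower) with DESeq2, to 2808 (1328 higher, 1480 lower) with DESeq2's local trend, and to 1569 (726 higher, 843 lower) against a fold of 1.2, which by construction leaves out small changes. For DESeq2 the cause was not tested. All 2491 and 2808 genes were also among the 5122. Of the genes called both in the main fit and under another setting, 0 changed direction. All settings draw on the same libraries, and the direction of genes that lost their call was not compared in this count. Same-numbered libraries did not deviate together (correlation across genes -0.0427), so no effect shared by number was seen in expression. Whether same-numbered libraries were grown or prepared together is not given in the labels. With the replicate block 4949 genes were called (2476 higher, 2473 lower) and camera called 16 lists. Without genes of the shifted runs 4456 were called, and without genes with a word in the 3′ UTR 4316, where the glypicans had too few members left to test. GDPD5 stayed past the threshold in all 15 settings that test it, at log2 fold changes from -1.14 to -0.82. Of 160 other named genes 117 kept their call and direction in every setting that tests them, and 0 reversed; of 93 lost or gained calls, 38 were lost against a fold of 1.2 and 12 with DESeq2. Camera called 16 lists, 16 to 18 with 1 library left out, and 0 with an estimated correlation, which also missed every planted list in simulated data of this design. Those planted lists held only small fold changes, so they cannot show whether lists with larger changes would be missed too. The simulated genes were drawn independently, so the planted lists cannot decide between the 2 correlation settings for lists of correlated genes. Fry called 16 lists, 14 of them shared with camera, without the mitochondrial and ribosomal lists and with neuronal differentiation markers and matrix proteases added. Camera added the actomyosin and stress response lists without shGDE2 replicate 2, and the actomyosin list without genes of the shifted runs. In simulated data of this depth and number of libraries 52% of the genes with the smallest planted fold were recovered; which of the 2 limits the test was not tested.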

Other observations

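The tests of GC content, base composition, runs and list members in this part were chosen after the results were seen; the predictions for genes under 5 CPM were fixed before those genes were looked at. Hedgehog pathway genes, chosen after their values were seen, moved with the loss of HHIP: GLI2, a transcription factor of the pathway, fell from 26.8 ± 0.24 to 16.8 ± 1.2 CPM (log2 fold change -0.68 ± 0.10, edgeR adjusted p = 8.51e-11), the co-receptor BOC fell from 18.4 ± 4.8 to 11.9 ± 0.52 CPM (-0.62 ± 0.12) and GLI3, inside the run on chromosome 7, fell by 0.25 on the log2 scale, while the receptor PTCH1 rose by 0.31 ± 0.13 (adjusted p = 0.0452) and SMO by 0.18. CDON (adjusted p = 0.542) and GAS1 (adjusted p = 0.399) were not past the threshold. RDH10, the retinol dehydrogenase that acts before ALDH1A1 in retinoic acid synthesis, rose from 64.6 ± 1.7 to 209 ± 5.3 CPM (log2 fold change 1.69 ± 0.05); it lies inside the run on chromosome 8, whose median was 0.25. Of the other retinoid genes looked at with it, the retinol dehydrogenase RDH11 (0.01 ± 0.06, adjusted p = 0.930) and the retinoic acid target HOXB2 (-0.01 ± 0.07, adjusted p = 0.911) were not past the threshold.

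Among 69 groups of genes that share a symbol stem, camera called 2. The collagen genes (COL) had 8 of 28 members higher and 10 lower (adjusted p = 0.00198), and the large ribosomal subunit genes (RPL) had 29 of 48 higher and 0 lower (adjusted p = 0.0311); 0 of the 69 were called with an estimated correlation, where every adjusted p was 0.897 or more. The zinc finger genes (ZNF) were more often higher (77 of 393) than lower (20), a list not called by camera (adjusted p = 0.324).

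For the 7 shifted chromosome runs, bias from GC content, transcript length or expression level is argued against, since every run kept at least 71.0% of its median after regression on all 3. A DNA copy number difference between the control and the knockdown cells is a candidate explanation. Of 197 weakly expressed genes in the runs that were not used in the search, 64.5% lay on the side of their run (127 genes, exact 95% interval 57.4% to 71.1%). The share passed the minimum fixed in advance, but its interval reaches below that minimum. Weakly expressed genes outside the runs were not compared. The runs differed in the share on their side, with only 17 of 32 such genes on the side of the run on chromosome 7 (median -0.07) and 10 of 10 on chromosome 12 (median -0.54). Regional gene regulation would shift these genes to the same side and stays open, as no DNA was measured. Inside the runs 60.1% of the tested genes changed, against 35.9% outside, so a run-wide shift could concern only part of the changed genes there, and not those that moved against their run, such as PTPRC.

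The lower level of genes with ATGACAC or TGACACA in the 3′ UTR is not explained by base composition, since the lowest z among 418 other words of the same bases was -4.64, nor by the shifted runs, since the z of ATGACAC was -9.20 without their genes. A candidate explanation is seed pairing of the hairpin's guide strand, whose sequence is not given in the sources used here: a guide matching the GDPD5 coding sequence at ATGACACA would carry both words as its seed sites. As fixed in advance, 226 genes under 5 CPM with a word had a lower median than 1161 with none, by a difference of -0.11 (1-sided permutation p = 0.0121, 95% bootstrap interval -0.20 to 0.0083, which includes 0). Unlike the search, this comparison was not adjusted for UTR length, GC content or expression level, so a difference in these between the groups may contribute. The match in GDPD5 weighs little, as 9.39% of 12092 protein-coding genes hold ATGACACA in a transcript, and a change in a cellular microRNA with this seed stays open. Genes with a word made up 21.1% of the lower genes searched, an excess of 184 genes (8.39%), so such pairing could account directly for a small part of the decreases. The share differed between lists. A word was held by 3 of the 4 lower neuronal differentiation markers searched and by 4 of 7 lower interferon-stimulated genes. It was held by 2 of 14 lower immediate-early genes and 0 of 5 lower Wnt members. For the few neuronal markers, such pairing and an effect of GDE2 loss cannot be told apart.

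Most of the lower extracellular matrix, mesenchymal and integrin genes lie outside the shifted runs, and most of those searched hold no word in the 3′ UTR. Of 46 lower members 6.52% lie in the shifted runs (exact 95% interval 1.37% to 17.9%), and of 42 searched 23.8% hold a word in the 3′ UTR (12.1% to 39.5%). Among all searched genes 14.1% hold a word, and among all lower genes searched 21.1%. Of all 13583 tested genes 994 lie in the runs. With such shares among all genes a minority was likely beforehand, so these counts do not decide what caused the fall. Camera at the preset correlation still called these lists without genes of the runs and without genes with a word. Indirect effects of a regulator that is itself altered by either pattern remain open. So does an effect of GDE2 loss, which may act on these genes but is confounded with the hairpin and the line, since 1 hairpin was compared with 1 control.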
